A study of Homo sapiens with 9 samples.

How the data were processed

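Gene expression was measured in U87 cells, a human glioblastoma-derived line grown as glial-like cells, on 9 single-colour Agilent microarrays. The labels gave 3 groups of 3 arrays: untreated controls (0 µg/mL), fluoride at 0.095 µg/mL and fluoride at 0.22 µg/mL, all harvested after 10 days. Per the labels' protocols, the medium was changed during exposure, total RNA was column-purified, only RNA of sufficient integrity was carried on, and Cy3-labelled cRNA was hybridised. The series design states 3 independent experiments on different cell passages. Whether a replicate number marks the same passage in every group is not given in the sources used here, so p-values measure the spread among these arrays.

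Each array came as a scanner table. Per the file headers, the spot intensity values were extracted with Agilent Feature Extraction 12.0.3.1, which had subtracted the background and corrected spatial trends in the processed signal, with no scaling between arrays. The submitters' processing notes name the same software without a version. The deposited tables also held raw median intensity of each spot and of its local background, and flags (0 or 1 marks of another kind) for outlier spots, saturation and spots well above background. The mean spot signal was not used here because the tables analysed do not list that column, so the normexp background correction was run on the median signal. The series also carried a deposited value table in log2 units, whose processing is not given in the sources used here. Each of its columns correlated best with its own array's scanner signal (Spearman 0.957 to 0.994 across spots, against at most 0.915 for another array). Its column medians lay between 5.553 and 5.565 and its quantiles were nearly equal, so its scale is log2, it is not centred per gene, and the exact steps behind it remain unknown. It served as an alternative only.

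Of 62976 spots per array, 58717 were not control spots and held 50599 distinct probes, of which 902 were printed 10 times. Outlier-flagged spots were left out and the spots of a probe averaged, which removed 100 probes. Symbols were assigned by matching unversioned RefSeq accessions to a gene table of assembly GRCh38.p14, used for names, gene spans and gene order only, because the array headers name hg19. This named 30217 of 50499 probes (59.8%), for 21717 genes; all 7292 probes with Ensembl transcript identifiers stayed unnamed. The main values were log2 of the processed signal minus each array's 75th percentile of it. Probes well above background on all 3 arrays of at least 1 group were tested, which left 23112 probes and 13749 named genes. A gene was represented by its tested probe with the highest mean signal over the 9 arrays. Among 3473 genes with several tested probes, 133 had probes past the threshold in opposite directions for the average of both doses.

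All 9 arrays entered a single limma 3.58.1 fit (R 4.3.3) with a mean per group, moderated by eBayes, with no covariate. Contrasts were each dose against control, the higher against the lower dose, and the average of both doses against control; a moderated F-test covered any difference among the 3 groups. Benjamini-Hochberg adjustment ran over all tested probes, with the threshold at 0.05. Before the data were examined, 32 gene lists, the comparisons, their alternatives and the naming rule were fixed. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data and with fry. The naming rule took, for each dose against control, the 10 largest increases and the 10 largest decreases among genes past the threshold that were well above background on all 6 arrays compared and whose groups did not overlap, plus up to 3 genes per direction well above background on all arrays of 1 group and none of the other. For the other comparisons it took 5 per direction, filled by unadjusted p where too few passed, among genes with the same non-overlap and detection and a fold of at least 1.5. It also took up to 4 members of each list by unadjusted p. Most, not all, of the genes it took are named in the text. With 3 arrays against 3, chance keeps the groups apart for 10% of probes. A gene not well above background on any array of a group has only a bound there: the bright group's mean was set against the mean, per array of the dim group, of the higher of the probe's own signal and the lowest signal among probes well above background.

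Alternatives were quantile normalization, median centring, normexp (offset 50) followed by either scaling, no filter on dim probes, a filter over all 9 arrays, the replicate number as a block, eBayes with trend and robust, array weights, the deposited value table, 1 probe per gene, fits to only the 2 groups compared, an unadjusted p under 0.05 with a fold of 1.5, and leaving out each of the 9 arrays. Chosen after seeing the data were a replicate block among the 6 fluoride arrays, fluoride numbers as a random block, the mean of equal-numbered fluoride arrays, and removal of a trend on gene span. Replicate numbers were checked for pairing by correlating arrays' deviations from their group means over probes. Equal-numbered arrays of the 2 doses gave r of 0.361, 0.709 and 0.617, and no other pair of those groups exceeded 0.0298, so the numbers paired the 2 doses. Equal-numbered control and fluoride arrays gave -0.138 to -0.00658 and were not paired.

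The fit was tested on simulated data with 100 probes changed 2-fold and 100 changed 4-fold among the 23112. It recovered 11% and 73% of them for 0.095 against control, 20% and 75% for 0.22 against control, 15% and 82% for 0.22 against 0.095, 31% and 80% for the average of both doses, and 6% and 79% for any difference among groups. In the data 36.1% and 37.4% of probes passed at 0.095 and 0.22 µg/mL against control. The adjusted threshold is stricter where few probes change, so the shares recovered do not carry over to comparisons with so many changes. With nothing changed, the 5 tests gave at most 1 false call. In a simulation of lists at 0.22 against control over 13749 genes, the 1 list moved was recovered and 0 of the others were called. In these simulations probes varied independently and arrays were not paired. The list simulation therefore cannot show how camera at the preset correlation does where genes move together. In the data the median estimated correlation of the lists was 0.108. Array number limits the precision: the median standard error of a dose effect was 0.268 on the log2 scale. Figures were drawn with matplotlib 3.10.9.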

Results

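The data were 9 one-colour arrays of total RNA from U87 cells, a human glioblastoma-derived line used as a model of glial cells. The cells had been left untreated or exposed for 10 days to fluoride at 0.095 or 0.22 µg/mL, with 3 arrays per group, and the question was how gene expression differed between exposed and unexposed cells and between the doses. The 75th percentile of the processed signal lay between 284.8 and 411.8 units. Between 42.8% and 48.5% of probes were well above background on 8 arrays, and 56.0% were on control replicate 1. The 3 controls sat on slide 1, read in scan 1, and the 6 fluoride arrays on slide 2, read in scan 2, so slide, scan and exposure cannot be told apart in any comparison with control. The first principal component held 59% of the variance and separated control from fluoride arrays, and the second held 18.8% and separated the replicate numbers of the fluoride arrays.

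**Figure D1:**
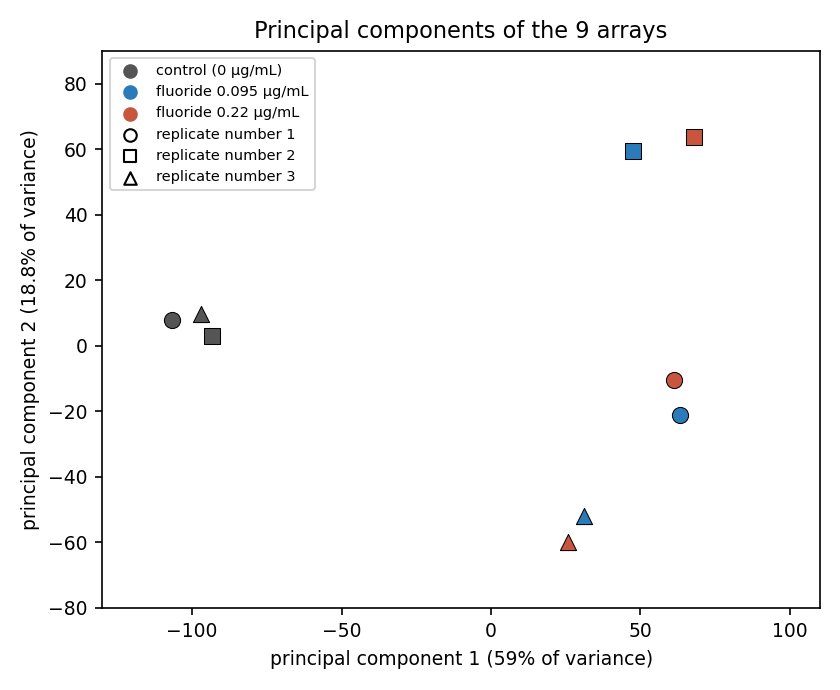
Principal components 1 and 2 of the 9 arrays, computed from the probes tested, with colour for the fluoride group and marker shape for the replicate number. The controls lie at -106.7 to -93.19 on the first component and the fluoride arrays at 25.77 to 67.86, and equal-numbered fluoride arrays of the 2 doses lie next to each other.

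In cells exposed to 0.095 µg/mL fluoride, EDIL3, ANGPT1 and CALCA were among the genes that rose most, and CCL3, CSF2 and ATF3 among those that fell most. EDIL3, a secreted integrin-binding protein, rose 10.6-fold (log2 change 3.41 ± 0.215 SE, n = 3 per group, limma adjusted p = 0.000359). ANGPT1, the ligand of an endothelial receptor kinase, rose 8.02-fold (3.00 ± 0.334) and CALCA, which encodes calcitonin and a related neuropeptide, rose 9.07-fold (3.18 ± 0.759, adjusted p = 0.0124). The chemokine gene CCL3 was 37-fold lower (-5.21 ± 0.698, adjusted p = 0.0016), CSF2, which encodes a granulocyte-macrophage growth factor, was 23.4-fold lower (-4.55 ± 0.474), and the stress-inducible transcription factor ATF3 was 15.8-fold lower (-3.98 ± 0.654), its 3 other probes standing at -4.22, -2.73 and -0.89. ADAMTS5, a protease that cleaves aggrecan, changed by -4.37 ± 0.291. CCL3 was at -5.99 without control replicate 1 and ATF3 at -4.69 without fluoride 0.095 replicate 2.

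Among the other largest increases at 0.095 µg/mL, 5 of the 10 were small RNAs: SNORA16B (3.47), SNORD3B-1 (3.42), SNORD26 (3.29), RNU4ATAC (3.14) and SNORA16A (2.99). A different probe of SNORD3B-1 showed 0.03 and did not pass. OSBPL8, a lipid transfer protein of the endoplasmic reticulum, and SOST, a secreted inhibitor of Wnt signalling, rose by 3.28 and 3.18, a second probe of OSBPL8 showing 2.19. The call on SOST was lost without control replicate 3 (adjusted p = 0.0605) or without fluoride 0.095 replicate 1 (0.054), and that on CALCA without fluoride 0.095 replicate 1 (0.0514). SOST was at 3.86 and 2.59 without fluoride 0.095 replicate 2 and 3, and SNORD26 was 16.3-fold higher without control replicate 2. Among other large decreases, the RNA helicase gene DHX37 changed by -4.48, SLURP2 by -3.93, KLHDC7B by -3.91 and the acid phosphatase gene ACP5 by -3.86. The organic anion transporter gene SLCO4A1 was 16-fold lower, and at a log2 change of -4.64 without fluoride 0.095 replicate 2, while SLURP2 was at -3.32 without control replicate 1.

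At 0.095 µg/mL, 8334 of 23112 probes (36.1%) passed the limma threshold, 2982 higher and 5352 lower, and 5269 of them changed at least 2-fold. Counted by the probe that represented each gene, 4803 of 13749 genes passed, 1702 higher and 3101 lower. The split between directions rested on the scaling, since quantile normalization called 3483 higher and 3941 lower and moved the median change of all probes from -0.21 to -0.05. The count was 4904 without fluoride 0.095 replicate 1, 5507 without control replicate 3, 5521 with no filter on dim probes and 14485 with array weights.

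Of the 32 gene lists fixed beforehand, 11 passed at 0.095 µg/mL by camera at the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.441). Medians here are given relative to the median of all genes tested. The NF-kappaB and inflammatory list fell most, with a relative median of -1.66, 15 of its 20 measured genes lower and 0 higher (camera adjusted p = 3.33e-05). The neutrophil chemokine gene CXCL2 changed by -3.06 ± 0.314, the signalling adaptor gene TRAF1 by -2.91 ± 0.312 and the apoptosis inhibitor gene BIRC3 by -1.80 ± 0.216. In the ATF4 and amino acid list, 14 of 18 genes fell (relative median -1.12, adjusted p = 0.000255), among them the serine synthesis enzyme PHGDH (-1.33), the stress sensor SESN2 (-1.95) and the glutathione-degrading enzyme CHAC1 (-2.73). In the immediate early list, 11 of 17 fell (-1.02, adjusted p = 0.000375), with IER3 at -2.46, the mRNA decay factor ZFP36 at -2.02, FOSL1 at -2.35 and EGR1 at -2.73. The leukocyte and microglia markers CD79A (-1.80), CD14 (-1.57) and CSF1R (-1.38) were also lower, but that list as a whole did not pass (adjusted p = 0.151, 3 of 6 lower). With an estimated correlation the adjusted p was 0.441 for the inflammatory, ATF4, immediate early and leukocyte lists.

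The heat shock and metallothionein lists were also lower at 0.095 µg/mL. In the heat shock list, 11 of 14 genes fell (relative median -0.73, adjusted p = 0.00192), with the chaperone genes DNAJB1 at -1.58, HSPH1 at -1.21 and HSPD1 at -1.09. Metallothioneins, small metal-binding proteins with closely related sequences, fell in 7 of 10 cases (-0.95, adjusted p = 0.00189), with MT1X at -1.84 ± 0.185 and MT1A at -1.27. Of the NRF2 target genes 9 of 18 fell (-0.53, adjusted p = 0.0195), including haem oxygenase HMOX1 (-1.68), GCLC (-1.68) and the cystine transporter gene SLC7A11 (-1.24). Ribosomal protein genes were lower in 21 of 29 cases (-0.42, adjusted p = 3.33e-05), with RPL13A at -0.91, and oxidative phosphorylation genes in 9 of 27 with 1 higher (-0.26, adjusted p = 0.0421, the relative median running from -0.35 to 0.00106 over the scalings), with UQCRC1 at -1.16 and SDHD at 0.97. With an estimated correlation the adjusted p was 0.441 for these lists and 0.647 for oxidative phosphorylation. Under quantile normalization the NRF2, ribosomal and oxidative phosphorylation calls ended (adjusted p of 0.151, 0.612 and 0.968).

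Mitosis and matrix genes moved the other way at 0.095 µg/mL. In the mitosis list 9 of 24 genes rose and 0 fell (relative median 0.65, adjusted p = 2.92e-05; adjusted p = 0.491 with an estimated correlation). The spindle motor gene KIF20A rose by 2.23 ± 0.412, the anaphase activator CDC20 by 1.77 ± 0.251, TOP2A by 1.64 and the centromeric histone CENPA by 1.31. The mitosis list also moved between fluoride arrays, by a median of 0.51 for number 1 against numbers 2 and 3. Its medians against control, likewise not set relative to all genes, were 0.45 at 0.095 and 0.52 at 0.22 µg/mL. In the extracellular matrix list 11 of 24 rose and 2 fell (1.06, adjusted p = 0.000108; 0.441 with an estimated correlation), with lumican (LUM) at 2.25 ± 0.223, COL5A2 at 1.81 and LAMB1 at 0.93, while COL4A2 was at -0.98. In the interferon list 3 of 19 rose and 2 fell (0.75, adjusted p = 0.0339; 0.441 with an estimated correlation): IFI6 (1.31), BST2 (1.23) and IFIT1 (1.30) rose, and IRF7, a transcription factor that induces interferon genes, was at -2.47. The interferon call ended under quantile normalization (adjusted p = 0.137) and without fluoride 0.095 replicate 2 (0.108).

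**Figure D2:**
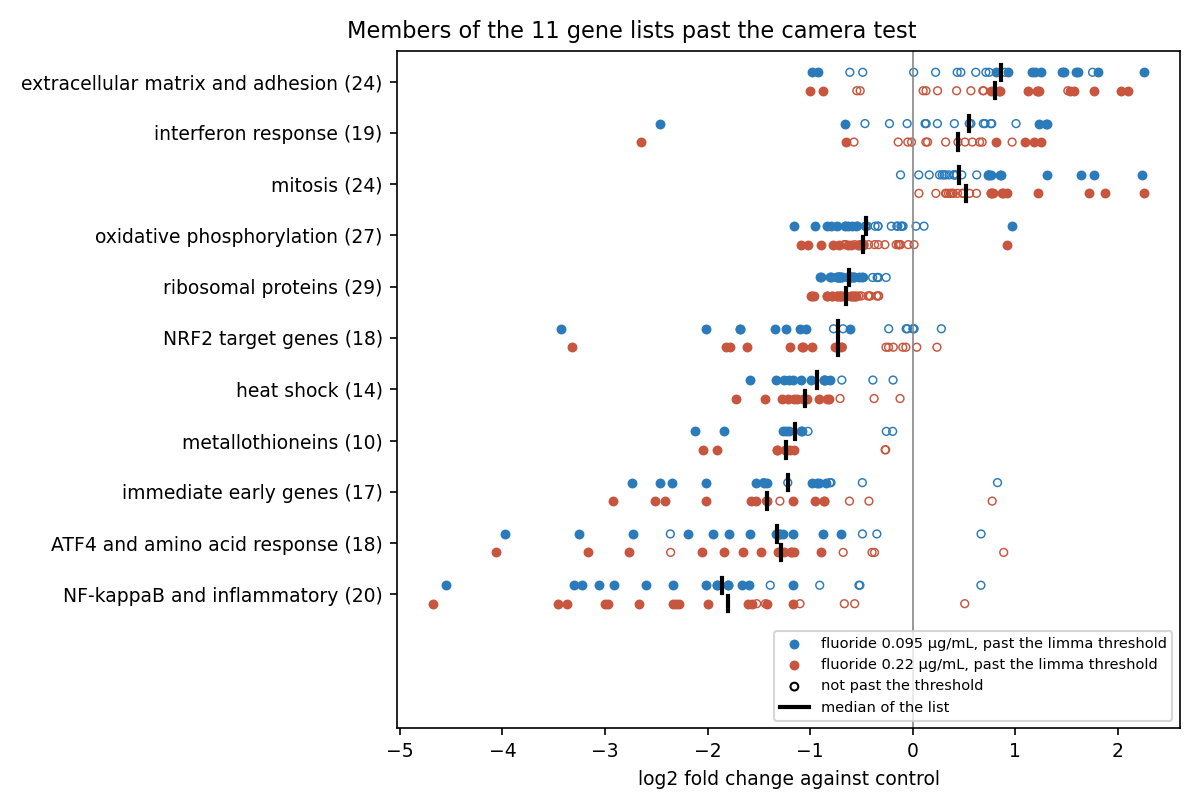
Log2 fold change against control (horizontal axis) of each measured member of the 11 lists that passed camera at 0.095 µg/mL, with the number measured in brackets; blue, 0.095 µg/mL; red, 0.22 µg/mL; filled points passed the limma threshold and black bars are list medians, not set relative to all genes. List medians run from -1.86 (inflammatory) to 0.855 (matrix) at 0.095 µg/mL and from -1.80 to 0.799 at 0.22 µg/mL; the interferon list passed at 0.095 µg/mL alone.

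At 0.22 µg/mL the largest changes named many of the same genes. OSBPL8 rose 10.8-fold (log2 change 3.43 ± 0.400 SE, n = 3 per group, limma adjusted p = 0.000916), EDIL3 10.3-fold (3.36 ± 0.215), SOST 8.82-fold (3.14 ± 0.807, adjusted p = 0.016) and ANGPT1 7.56-fold (2.92 ± 0.334). PTN, a heparin-binding growth factor of the nervous system, rose 7.34-fold (2.88 ± 0.204), PDK4, a kinase that shuts off pyruvate dehydrogenase, 7.49-fold (2.91 ± 0.250), and IGFBP4, which binds insulin-like growth factors, 7.81-fold (2.97 ± 0.303). CCL3 was 31.8-fold lower (-4.99 ± 0.698, adjusted p = 0.00145) and CSF2 25.6-fold lower (-4.68 ± 0.474).

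The remaining largest increases at 0.22 µg/mL were SNORD3B-1 (3.13, its other probe at -0.30 and not passing), CCDC144A (2.99) and SNORD26 (2.93). Other large decreases were SLURP2 (-4.37), the hair keratin KRT33B (-4.34), DHX37 (-4.32), ADAMTS5 (-4.30), SLCO4A1 (-4.12), KLHDC7B (-4.09) and ATF3 (-4.06). The call on SOST was lost without control replicate 3 (adjusted p = 0.0607) or fluoride 0.22 replicate 1 (0.0519). Without control replicate 1, CCL3 was at -5.77, KRT33B at -4.94 and SLURP2 at -3.76, and without control replicate 2 SNORD26 was at 3.67. Without fluoride 0.22 replicate 1, DHX37 was at -3.71 and SNORD3B-1 at 3.73, without replicate 2 ATF3 was at -4.68 and SOST at 3.82, and without replicate 3 DHX37 was at -5.18. Counted by the probe that represented each gene, 4926 genes passed at this dose (1697 higher and 3229 lower). In all, 8634 probes (37.4%) passed, 3074 higher and 5560 lower, and 5568 of them changed at least 2-fold. Quantile normalization called 3600 higher and 4268 lower, median centring 1574 higher and 5073 lower, no filter on dim probes 5745 in all and array weights 13528.

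**Figure D3:**
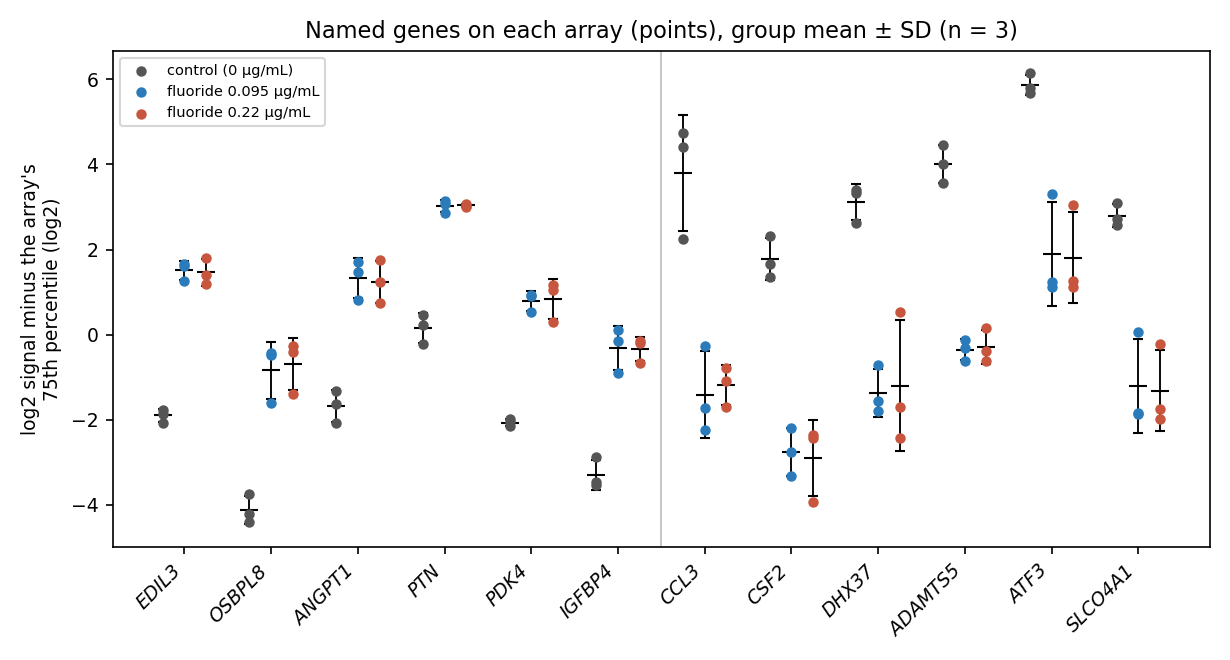
Normalised log2 signal (vertical axis, relative to each array's 75th percentile) of 6 named genes that rose and 6 that fell; points are arrays, horizontal bars group means and whiskers SD (n = 3). For each gene the 6 fluoride arrays lie on the same side of all 3 controls, which the naming rule required at the dose where it took the gene. ATF3 had control values of 5.678 to 6.141 and fluoride values of 1.118 to 3.315, the fluoride arrays with replicate number 2 being the highest at each dose.

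The gene lists at 0.22 µg/mL gave 10 camera calls, with the same 8 lower lists and with mitosis and extracellular matrix higher. With an estimated correlation 0 passed (lowest adjusted p = 0.437). The inflammatory list had 14 of 20 genes lower (relative median -1.60, adjusted p = 2.02e-05), with TRAF1 at -3.37, CXCL2 at -3.00 and BIRC3 at -1.57. The ATF4 list had 13 of 18 lower (-1.08, adjusted p = 0.000539) and the immediate early list 11 of 17 (-1.21, adjusted p = 0.000448), with EGR1 at -2.93. The leukocyte markers CD79A (-1.81), CD14 (-1.63) and CSF1R (-1.41) were lower beside them, the list not passing (adjusted p = 0.149). Heat shock genes fell in 11 of 14 cases (-0.84, adjusted p = 0.00191), metallothioneins in 8 of 10 (-1.03, adjusted p = 0.00122), NRF2 targets in 10 of 18 (-0.52, adjusted p = 0.0121), ribosomal proteins in 21 of 29 (-0.44, adjusted p = 2.02e-05) and oxidative phosphorylation genes in 10 of 27 with 1 higher (-0.28, adjusted p = 0.0297). Mitosis genes rose in 10 of 24 cases with 0 lower (0.73, adjusted p = 5.72e-06), with KIF20A at 2.25 and CDC20 at 1.88, and matrix genes in 12 of 24 with 2 lower (1.00, adjusted p = 0.000144), with LUM at 2.09 and COL5A2 at 1.77. With an estimated correlation the adjusted p was 0.437 for 9 of these lists and 0.601 for oxidative phosphorylation. Under quantile normalization the NRF2, ribosomal and oxidative phosphorylation calls ended (adjusted p of 0.151, 0.57 and 0.995). The interferon list did not pass here (adjusted p = 0.0611), and its shift between the doses was not past the threshold either (adjusted p = 0.862).

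Adjusted over the list alone, 15 inflammatory, 14 ATF4, 13 immediate early, 12 heat shock, 8 metallothionein, 10 NRF2, 23 ribosomal and 10 oxidative phosphorylation genes were lower at 0.095 µg/mL, and 9 mitosis and 12 matrix genes higher. At 0.22 µg/mL the same count gave 15, 14, 12, 12, 8, 10, 23 and 11 lower, and 10 and 12 higher. For 7 lists, namely inflammatory, ATF4, immediate early, heat shock and metallothionein lower and mitosis and matrix higher, the camera call and direction held under every scaling and background correction tried at both doses, all at the preset correlation. With an estimated correlation none of them passed (adjusted p of 0.437 to 0.491).

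The other 21 lists did not pass at either dose; camera adjusted p at 0.095 and 0.22 µg/mL stand in brackets. Among astroglial markers (0.113 and 0.116), 3 genes rose and 1 fell at each dose, with relative medians of 0.54 and 0.47. NDRG2 was lower (-1.24 and -1.30), against the direction of that list. In the endoplasmic reticulum stress list (0.0663 and 0.0922) the protein-folding enzymes PDIA6 (1.28 and 1.33) and PDIA4 (1.81 and 1.56) and the degradation factor EDEM1 (1.91 and 2.10) rose. In the hypoxia list (0.139 and 0.146) the adenylate kinase AK4 (2.31 and 2.42) and the carbonic anhydrase CA9 (1.01 and 1.09) rose and NDRG1 fell (-0.95 and -0.89). Under quantile normalization the reticulum list passed as higher (0.0155 and 0.0164), and so did the hypoxia list (0.0391 and 0.0347). With the 75th percentile scaling and an estimated correlation, the adjusted p was 0.491 and 0.536 for the reticulum list and 0.709 and 0.687 for the hypoxia list. Among antioxidant enzymes (0.721 and 0.633), catalase (CAT) rose by 1.77 at both doses, while 3 genes rose and 6 fell at 0.095 µg/mL and 4 rose and 8 fell at 0.22 µg/mL. GNA11 rose by 2.04 and 2.10 among G protein genes (0.196 and 0.182), and NBN by 1.43 at both doses among DNA repair genes (0.827 and 0.633). The DNA repair list was mixed, with 5 genes higher and 5 lower at 0.095 µg/mL, and 6 higher and 4 lower at 0.22 µg/mL. The amyloid precursor gene APP fell (-1.77 and -1.78) in the neurodegeneration list (0.721 and 0.704). That list was mixed, with 3 genes higher and 4 lower at 0.095 µg/mL, and 4 higher and 3 lower at 0.22 µg/mL. The protease inhibitor TIMP1 (-1.30 and -1.37) fell among metalloproteinases and inhibitors (0.721 and 0.732), and BID (-1.21 and -1.24) among apoptosis genes (0.196 and 0.168).

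Of the remaining lists, DNA replication (0.914 and 0.906) held MCM10, which rose by 1.78 and 1.73, and MCM5, which fell (-2.18 and -2.19). Neuronal markers (0.892 and 0.906) held the synaptic vesicle gene SYT1, which rose by 2.11 and 2.16, and the postsynaptic scaffold DLG4, which fell (-1.88 at 0.095 µg/mL). CLDN7 fell (-1.38 and -1.49) among epithelial markers (0.175 and 0.233). Adjusted p was 0.206 and 0.305 for oligodendrocyte markers, 0.965 and 0.906 for endothelial markers, 0.151 and 0.115 for glycolysis, 0.2 and 0.233 for the tricarboxylic acid cycle, 0.721 and 0.633 for cholesterol synthesis, 0.721 and 0.778 for autophagy and lysosome, 0.668 and 0.633 for ion pumps, and 0.892 and 0.838 for p53 targets.

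Some genes were well above background on all arrays of 1 group in a comparison and on none of the other, so only a bound on their change is available. SOX9, a transcription factor of glial cells, was well above background on no control array and was at least 8.92-fold higher at 0.095 µg/mL (limma adjusted p = 0.000359) and at least 7.23-fold higher at 0.22 µg/mL (0.000333). GALNT15, a glycosyltransferase, was at least 5.71-fold and 7.17-fold higher, and PURG at least 5.71-fold and 5.77-fold. In the other direction, ZP4 was at least 9.91-fold and 12-fold lower, GPR84 at least 10.5-fold and the hair keratin KRT33A at least 6.97-fold lower at 0.095 µg/mL, and C5orf58 at least 8.41-fold and the elastase inhibitor PI3 at least 7.3-fold lower at 0.22 µg/mL.

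Averaged over both doses, the largest changes were again in EDIL3 and CCL3. The fit took the 6 fluoride arrays as independent, although equal numbers paired the doses. Standard errors and p-values for this average and for the F-test may therefore be too small. The comparisons of each dose with control drew on the same estimate of the spread, so their p-values may be affected too. EDIL3 rose by 3.39 ± 0.187 (SE, n = 6 fluoride and 3 control arrays, limma adjusted p = 9.43e-05), OSBPL8 by 3.35 ± 0.347 and SOST by 3.16 ± 0.699. CCL3 changed by -5.10 ± 0.605 (adjusted p = 0.000499), CSF2 by -4.61 ± 0.411, DHX37 by -4.40 and ADAMTS5 by -4.34. SNORD3B-1 (3.27) completed the largest increases together with SNORD26 (3.11, and 3.85 without control replicate 2), and CCL3 was at -5.88 without control replicate 1. Counted by the probe that represented each gene, 6020 genes passed. In all, 10422 probes (45.1%) passed, 3751 higher and 6671 lower. With the fluoride numbers as a random block 8410 passed for the average, 7692 at 0.095 µg/mL and 8046 at 0.22 µg/mL. With the mean of equal-numbered arrays 9411 passed for the average. Quantile normalization called 4421 higher and 5171 lower, and median centring 2232 higher and 6155 lower, so the split rested on the scaling. The moderated F-test for any difference among the 3 groups called 7598. The F-test count was 4707, 4593 and 4275 without control replicate 1, 2 and 3, 4778 with no filter on dim probes and 14199 with array weights.

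The differences from control ran in parallel at both doses, whose arrays shared a slide. Of the 23112 probes, 2696 were called higher at both doses against 396.6 by chance overlap, and 4852 lower at both against 1288. Across probes, which are not independent replicates, the log2 changes of the doses correlated at r = 0.960 (covariance 0.905). Unchanged groups simulated against the same controls gave r = 0.501 (covariance 0.06), so part of the excess overlap may come from the shared controls, which were too few to be split. The pairing of equal-numbered arrays across the doses and the shared slide may raise the agreement too. The chance overlap allows for neither.

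**Figure D4:**
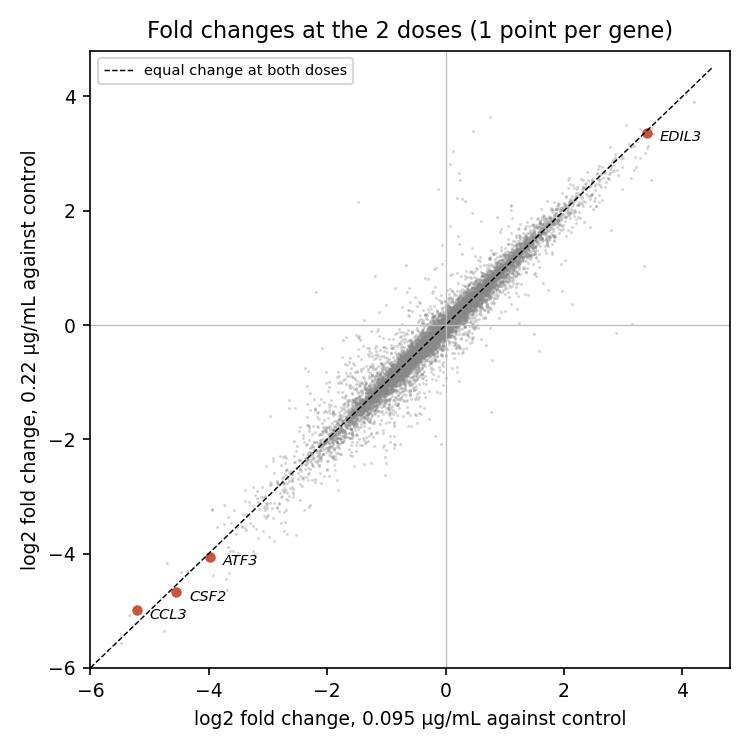
Log2 fold change against control at 0.22 µg/mL (vertical axis) plotted against that at 0.095 µg/mL (horizontal axis), 1 point per gene, with named genes marked and a line of equal change. Across probes the correlation was 0.960, and named genes such as EDIL3 (3.41 and 3.36) and CCL3 (-5.21 and -4.99) lie near the line.

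Between the doses, no gene differed past the threshold by limma. Among genes whose groups did not overlap and that met the naming rule's fold minimum, those with the smallest unadjusted p were NUDT13, a nudix hydrolase (0.90 ± 0.262, n = 3 per group, limma adjusted p = 1), and ACVR2A, an activin receptor (-0.68 ± 0.170, adjusted p = 1), with PHKG1 at 0.60, SNORD31 at 1.05, TRAF3 at -0.73, MMP28 at -0.67, CASKIN2 at -0.65 and PABPC3 at -0.62. By limma 0 of 23112 probes passed (smallest adjusted p = 0.139), with 330 (1.43%) at an unadjusted p under 0.05. That share lies below the 0.05 expected with no difference and independent arrays. A replicate block among the 6 fluoride arrays, whose numbers paired the doses, gave 0 of 20932, with 792 at an unadjusted p under 0.05, while the fluoride numbers as a random block called 28 probes, 12 higher and 16 lower. Of the 32 lists 0 shifted (lowest camera adjusted p = 0.76; 0.996 with an estimated correlation), and 0 with the block (lowest 0.204; 0.968 with an estimated correlation). In the main fit, which took no account of the pairing, the median 95% confidence interval reached 0.61 on the log2 scale, or 1.52-fold, either way. An interval that allows for the pairing is not given. Without 1 fluoride array the count reached 13 (without fluoride 0.22 replicate 1), and mitosis genes then passed as lower (camera adjusted p = 0.0184). They passed as higher without fluoride 0.095 replicate 1 (1.15e-06) or 0.22 replicate 3 (0.00379). These calls are at the preset correlation, and an estimated one was not run for them. Such fits hold 1 number at 1 dose only, and the mitosis list was higher in number 1 than in numbers 2 and 3 (median 0.51).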

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

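Quantile normalization had been chosen beforehand as an alternative scaling; the comparison by replicate number and the tests in this part, other than scaling between replicate numbers, were chosen after the results were seen.

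The negative control spots, which match no human transcript and enter no comparison, were brighter on the fluoride arrays. Their mean net signal was 47.3 ± 3.25 (SD, n = 6) on fluoride arrays and 36.0 ± 1.63 (n = 3) on controls, a difference of 11.3 (exact permutation test, 2-sided p = 0.0119, the smallest the 84 splits allow).

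The fluoride and control arrays differed in 10422 probes in the average of both doses, and 3 explanations were weighed. Scaling between arrays as the whole cause is argued against by the 9592 probes still called in the average of both doses under quantile normalization. An effect in proportion to the dose is argued against as the whole cause as well. Among these probes the median change at 0.22 over that at 0.095 µg/mL was 1.03. It was at most 1.15 in a pair of equal-numbered arrays, where the doses differ 2.32-fold. A shift between the slides would enter both doses alike and draw this ratio towards 1. The ratio therefore cannot exclude a proportional effect that adds to such a shift. Slide, scan and labelling batch cannot be told apart from fluoride: spike-in RNA from the labelling kit was brighter on control arrays by 0.86 on the log2 scale (exact permutation test, 2-sided p = 0.0119). The 75th percentile scaling did not remove this gap. Relative to that percentile the spike-ins stood at 3.34 on control and 2.38 on fluoride arrays (log2, exact permutation test, 2-sided p = 0.0119). An effect of fluoride that had levelled off below 0.095 µg/mL stays open beside a batch difference, untested.

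The inflammatory, immediate early, ATF4, heat shock and 4 other lists were lower on the fluoride arrays. A trend on the length of the gene's span is argued against as the whole cause, since 7 of the 8 lists lower at 0.22 µg/mL stayed past the threshold once it was removed, oxidative phosphorylation being lost. These calls rest on the preset correlation, and with an estimated correlation none of the 8 passed (adjusted p of 0.437 to 0.601). The state of the cultures at harvest may contribute and cannot be told apart from fluoride: the ATF4 list also moved between fluoride arrays, by a median of 0.68 for number 2 against numbers 1 and 3 (camera adjusted p = 0.0095; 0.607 with an estimated correlation), and the files give no measure of the cultures' state at harvest. Fluoride itself stays open.

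The fluoride arrays differed by replicate number, 4626 of 23112 probes passing against the spread within equal-numbered pairs, which is not the spread between cultures. Scaling is argued against by 4800 probes under quantile normalization, and position on the slide by a highest correlation of 0.976 for arrays of different numbers in a slide row, below the lowest of 0.985 for equal numbers. A culture or preparation shared by equal numbers stays open and cannot be told apart from any other source tied to the number: deviations from the group means correlated at 0.361 or more in all 3 equal-numbered pairs, which restates the pattern. No biological explanation was tested.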

How the results depend on the processing

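The fluoride numbers as a random block, the replicate block among fluoride arrays, the mean of equal-numbered arrays and the span correction were chosen after the data were seen. Of the results for list calls past the threshold at a dose, under alternatives, 445 kept their direction and side of the threshold and 59 lost the threshold, 21 of those with the estimated correlation; of the named gene results, 5814 kept both, 357 lost and 32 gained the threshold, and 1 reversed, PFKP at 0.095 µg/mL with the deposited value table (0.016, adjusted p = 0.949). For 0.095 and 0.22 µg/mL against control and the F-test, no filter on dim probes gave 5521, 5745 and 4778 probes, array weights 14485, 13528 and 14199, and 1 probe per gene 5028, 5147 and 4510 (6172 for the average of both doses), the last because fewer probes were tested. Leaving out 1 array gave 4904 to 8977, 5942 to 9162 and 4275 to 8527, and 7500 to 11112 for the average, with fewer arrays in each. Between the doses, array weights gave 2, only the 2 groups 3, the random block 28, an unadjusted p under 0.05 with a fold of 1.5 gave 289, and leaving out 1 array 0 to 13. The correlation between doses was 0.984 with normexp and quantile normalization, 0.982 with normexp and the 75th percentile, 0.851 with no filter, 0.984 with probes above background on all 9 arrays, 0.941 with array weights, 0.980 with the value table, and 0.913 to 0.960 without 1 array. At each dose 0 lists passed with the estimated correlation and 22 with fry, which compares no list with other genes; between the doses 0 to 3 passed without 1 array. Except where named, the cause was not tested. Slide and scan as a block was not run: it could not be fitted for fluoride against control, and both doses lie on 1 slide.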

Other observations

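The comparisons by replicate number, of RNA classes and of neighbouring genes, the mean of equal-numbered arrays and the random block were chosen after the data were seen; the counts of other groupings were not.

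Fluoride arrays of replicate number 2 stood apart from numbers 1 and 3 at both doses, with 5705 probes past the limma threshold, 2770 of them higher. Each number is held by a pair of arrays that varied together and may share a culture or preparation. Standard errors and p-values by number therefore measure the spread within such pairs, not the spread between cultures. The stress transcription factor gene DDIT3 was higher by 3.29 ± 0.125 (SE), the proton pump subunit gene ATP6V0D2 by 3.59 ± 0.142 and CLDN14 by 3.24 ± 0.118. MARS1, which charges the methionine transfer RNA, was at -3.11 ± 0.112, and the small RNAs SNAR-F and VTRNA1-3 were at -3.74 and -3.43. In the DNA replication list 14 of 23 genes were lower (median -0.80, camera adjusted p = 1.44e-06), in glycolysis 10 of 19 and in hypoxia 9 of 18 (0.0095 each). With an estimated correlation the adjusted p was 0.607. Number 3 differed from 1 and 2 in 4178 probes, with the inflammatory list lower (median -0.48, adjusted p = 0.00327; 0.648 with an estimated correlation). Number 1 differed from 2 and 3 in 0 probes by limma, but its lists shifted by camera: mitosis higher (median 0.51, adjusted p = 4.19e-11; 0.783 with an estimated correlation), DNA replication higher (0.35, 1.63e-05; 0.816) and ATF4 lower (-0.39, 0.000139; 0.783).

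Of 13 small nuclear RNA genes 7 rose and 0 fell in the average of both doses (median log2 change 2.11), and of 160 small nucleolar RNA genes 16 rose and 40 fell (median -0.31). The small nucleolar genes did not differ from other genes past the threshold (camera p = 0.906; 0.977 with an estimated correlation), protein-coding genes having a median of -0.20, and the small nuclear genes were not tested as a class. Log2 changes of neighbouring genes in the average of both doses correlated at 0.161 across genes, and at 0.119 once a trend on gene span was removed, against at most 0.0231 in 200 shuffled orders. For genes 20 places apart the values were 0.0843 and 0.0572, against at most 0.0273. Between the doses they were 0.0258 for neighbours and -0.0108 at 20 places. The cause was not tested. The 20% of genes with the shortest spans had a median of -0.41 and the 20% with the longest 0.06.

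Other groupings of the same arrays were counted. For 0.095 µg/mL against control the real grouping called 8334 probes and the highest of the others 0, and for 0.22 µg/mL 8634 and 0; each has 10 groupings, of which 1 called as many, too few for a share under 0.05. Between the doses the real count was 0, so all 10 groupings had to call as many and the share decides nothing. The highest other count was 1, and also 1 among the 4 groupings that part all 3 pairs. For the average of both doses 2 of 100 drawn groupings, of 840, called as many as the real 10422 (highest other 12577), and for any difference among the groups 4 of 100, of 280, called as many as 7598 (highest other 13170). Chance is excluded for both only if the 6 fluoride arrays are taken as independent, whereas equal numbers paired the doses (r of 0.361, 0.709 and 0.617); with the 3 numbers as units there are 10 groupings, too few for a share under 0.05. The mean of equal-numbered arrays gave 9411 probes for the average, and the fluoride numbers as a random block 8410 for the average and 5996 for any difference. Every drawn grouping as large kept the 3 controls together and so followed the slide, while the highest with controls parted was 1. This points to a structure of the arrays by slide or exposure, and no within-slide value can be had.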
